A study of Mus musculus with 6 samples.

How the data were processed

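The samples were CD45-enriched cells from serrated polyps and from the surrounding cecum of 3 HBUS mice, 3 polyp and 3 surrounding samples, and the study's design text states that the samples with the same mouse number came from the same animal. Per the labels' protocols, biotin-labelled cRNA was prepared from total RNA and hybridised to an Illumina mouse reference BeadChip. The deposited scanner table holds, per the file headers, 1 intensity per probe and array on a linear scale, with no negative value and a lowest signal between 79.2 and 84.9 on each array, so that a background level remained in the values. Beside each intensity the deposited table gives a detection p-value, rounded to 2 decimals. A further deposited table holds the authors' processed intensities of the same arrays. Over all 25697 probes these differed by at most 0.005 from a quantile normalization of the scanner intensities on the linear scale with no background subtraction, and their array medians lay between 104.25 and 104.32. The lowest correlation of a processed column with its own array was 0.99878 and the highest with another array 0.99138. The submitters' processing notes name GenomeStudio and limma 3.14.4 without saying what each was used for. No genome build is given in the sources used here, so no coordinates are printed.

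Analysis was done in R 4.3.3 with limma 3.58.1. The scanner intensities were corrected by limma's normexp method, with the background estimated from the detection p-values and an offset of 16, then quantile normalized and put on the log2 scale. The offset and the background step set the size of a fold change of a dim probe. Probes with a detection p-value under 0.05 on at least 3 of the 6 arrays were kept, 13409 in all, and 12288 were removed. Probes were named from the platform annotation, which gave 1 symbol for 23978 probes and several for 0, and did not list 1719. Of the named probes, 23962 were matched by gene identifier to the mouse RefSeq gene table of GRCm38.p6, used for names only, and 0 symbols changed. The tested probes with a name numbered 12641 and stood for 9246 genes. For a gene with several tested probes the brightest over the 6 arrays was used. Of 2438 such genes, 199 had a probe that passed the test and another that did not, and 1 had probes called in both directions. Of the changed probes, 77 had no gene name. All other tested probes of the genes that the rule below picked had the same sign as the brightest; those of other genes named in the text were not compared.

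The model had terms for mouse and for polyp against surrounding, and was fitted with lmFit and eBayes. Adjusted p-values are Benjamini-Hochberg values over all tested probes, with a threshold of 0.05, and the tests are two-sided. With 2 residual degrees of freedom, eBayes added 4.04 from its prior, so that the tests and SEs rest on variances shared across probes. At an unadjusted p under 0.05, 3726 probes passed. The pairing was checked on the deviations of each sample from its group mean. They correlated by 0.571, 0.564 and 0.614 across probes between the samples of the same mouse, and by -0.122 to -0.468 between samples of different mice. Deviations sum to 0 within a group, so positive values within mice make those between mice negative on average. The negative values are therefore no separate evidence of pairing. By the array names, the samples of a mouse also lay side by side on the chip, the polyp sample first. The positive values thus cannot tell a shared mouse from a shared place on the chip. A probe with a detection p-value at or above 0.05 on every array of a group has only a bound there: the ratio given as "at least" sets the brighter group's mean against, per array, the higher of the lowest detected signal and the probe's own value. Such probes numbered 44 among those changed.

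Before the data were examined, lists were fixed for neutrophils, monocytes and macrophages, dendritic cells, T cells, regulatory T cells, B cells, plasma cells, NK and cytotoxic cells, mast cells and basophils, eosinophils, epithelial cells, goblet and secretory epithelial cells, fibroblasts, endothelial cells, smooth muscle cells and erythroid cells. Function lists covered inflammatory cytokines, neutrophil-attracting chemokines, other chemokines, IL-1 signalling and inflammasome, pattern recognition receptors, NF-kappaB targets, type I interferon response, MHC class II presentation, NADPH oxidase and phagocyte killing, antimicrobial proteins, extracellular proteases, the EGF receptor family, hypoxia and glycolysis, cell cycle, T helper and innate lymphoid genes, myeloid suppression, immediate early and heat shock genes and ribosomal proteins. Lists with at least 5 tested members were tested with camera against the 9246 tested genes, with a preset correlation of 0.01 and, as alternatives, with an estimated correlation and by fry, and p was adjusted over the 32 lists. An adjusted p given for a list in the text is that of camera with the preset correlation unless it is named otherwise. A count adjusted over the list alone repeats the Benjamini-Hochberg step within the list.

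The rule for genes named in the text was also fixed before the data were examined. It takes the 10 largest rises and 10 largest falls among named genes past the threshold that moved the same way in the 3 mice, leaving out predicted loci. It adds Ptprc and, of each list, up to 4 tested members with the smallest p. Members of a list that the detection filter removed are named only as not tested. Chil3 and the genes of the closing panels lie outside the rule and were named after their values were seen. This also holds for the members named as not passing in the NK and dendritic cell lists.

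The fit was run on 15 simulated data sets of 13409 probes, each with 200 probes changed by known amounts. With variances drawn from the fitted prior, 8.36% of changes of 0.5 log2 units, 85.3% of changes of 1 and 99.1% of changes of 2 were recovered, and 5.04% of the calls were false. An earlier form of this simulation took the shrunken variance of each probe as its true variance and gave 9.04% false calls, above the 5% aimed for, with 52.6%, 99.6% and 99.9% of the same changes recovered. The form with variances from the prior was added after this was seen. It makes the assumption that eBayes makes, so that its share of false calls lies near 5% by construction and does not test that assumption. With no change simulated, 0 probes passed. A list of 20 probes shifted by 0.6 had p = 1.41e-37 in camera and p = 0.00505 with an estimated correlation, and an unshifted list had p = 0.621 and p = 0.726. The simulated probes varied independently of each other, whereas the correlation estimated for the real lists reached 0.956, in mast cells and basophils. The simulation therefore does not show how camera with the preset correlation of 0.01 behaves on lists of correlated genes.

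The alternatives tried were no background correction, an offset of 50, the authors' processed values, median scaling, cyclic loess, 3 other filters on dim probes, no mouse term, mouse as a random block, a trended and robust prior, array weights, leaving out each mouse, and 1 probe per gene. The closing section gives their effect. All value columns of both tables were used.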

Results

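Gene expression was measured in leukocyte-enriched cells from the cecum of 3 HBUS mice, a strain in which serrated polyps, a type of epithelial outgrowth, were found in this part of the gut. From each mouse, cells were taken from a polyp and from the cecal tissue around it, which gave 3 polyp and 3 surrounding samples in pairs. Epithelial cells were first loosened with EDTA, the remaining tissue was digested with dispase, and cells carrying CD45, a surface protein of leukocytes, were held on a magnetic column. RNA of each sample was hybridised to 1 array of an Illumina mouse BeadChip, and all 6 arrays were on 1 chip. The median probe signal ran from 97.3 in the polyp sample of mouse 3 to 109.3 in the polyp sample of mouse 2. The same polyp sample of mouse 3 had the fewest detected probes, 12657 or 49.3% of the 25697 on the array, and the surrounding sample of mouse 3 the most, 13796 or 53.7%. The number of arrays, 3 in each group, limits the precision of every value below. Changes are given as polyp minus surrounding on the log2 scale, with the standard error (SE) of the limma fit over 3 pairs (n = 3) and limma's adjusted p.

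Ptprc, which encodes CD45, was read first, since it is the marker the cells were selected by. Its normalised log2 intensity was 4.91, 5.43 and 4.48 in the polyp samples of mice 1, 2 and 3, against 5.95, 6.22 and 5.61 in the surrounding samples. It was lower in the polyp sample of every mouse, by -0.99 ± 0.11 (SE, n = 3 pairs, limma adjusted p = 0.0052), and was not detected in the polyp sample of mouse 3 (detection p-value 0.13). A second, dimmer Ptprc probe was lower by -0.42 ± 0.13 and did not pass the test (limma adjusted p = 0.0986). The size of the change depended on the background step: the authors' processed values, which carry no background subtraction, gave -0.35 (limma adjusted p = 0.0135). With mouse left out of the model the change no longer passed the test (limma adjusted p = 0.13).

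The comparison of polyp with surrounding cells asks which transcripts of CD45-enriched cecal cells differ at the site of a polyp, within the same animal. The purity of the enrichment is not given and epithelial genes were bright on all arrays, so the values are those of the enriched samples, not of leukocytes alone. In polyp samples, 15 of 16 tested marker genes of T cells, 13 of 15 of B cells and 7 of 10 of NK and cytotoxic cells were lower, and 8 of 14 of neutrophils, 8 of 12 antimicrobial protein genes and 12 of 12 endothelial markers were higher. As lists, none of these passed the list test with a correlation estimated from the arrays (adjusted p from 0.384 to 0.424), and with mouse left out of the model 0 of the 16 T cell markers passed. That list test rests on 2 residual degrees of freedom and had little power. Of 13409 probes tested, 1399 changed, 620 higher and 779 lower, so that 44.3% of the changes were rises. The named probes among them belonged to 497 genes that rose and 627 that fell. All 1399 moved the same way in the 3 mice, which passing the test with 3 pairs makes likely. At least a 2-fold change was seen for 323 probes, 114 higher and 209 lower. With arrays scaled to the same median in place of quantile normalization, 407 probes rose and 1000 fell, so that 28.9% were rises. In that fit eBayes gave every probe the same variance (infinite prior degrees of freedom), so that its calls rest on the size of a change alone. The count changed with the model and with the mice used: it was 183 with mouse left out of the model, 412 without mouse 2, 534 without mouse 3 and 1927 without mouse 1. A fit without a mouse has fewer pairs and fewer residual degrees of freedom. Its prior also differed, with 7.27, 5.22 and 3.78 degrees of freedom without mice 1, 2 and 3, against 4.04. Counts without a mouse, here and below, therefore also follow power and prior, not that mouse alone.

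The largest rise was that of Reg3b, which encodes a C-type lectin secreted onto the gut surface that kills bacteria. It was 22.2-fold higher (4.47 ± 0.32 log2, SE, n = 3 pairs, limma adjusted p = 0.00247), with the smallest difference, 3.39, in mouse 2. A second, dimmer Reg3b probe rose by 1.24. Its relative Reg3g was 8.15-fold higher (3.03 ± 0.12) and was detected on only 1 of the 3 surrounding arrays. Sis, the sucrase-isomaltase of the small-intestinal brush border, was higher by 3.59 ± 0.31 and was likewise detected on only 1 surrounding array. Arg1, the arginase of alternatively activated macrophages and suppressive myeloid cells, rose 11.5-fold (3.52 ± 0.28) and was detected on 2 surrounding arrays. Osr2, a transcription factor of mesenchyme, had the lowest adjusted p of all probes and differed by 3.51, 3.46 and 3.46 in the 3 mice (3.48 ± 0.09, limma adjusted p = 0.000209). Myl7, a myosin light chain best known from the heart atrium, rose by 3.40 ± 0.23, and Lgals2, a galectin of gut epithelium, by 2.92 ± 0.34. The calprotectin subunits S100a9 and S100a8 of neutrophils rose by 2.91 ± 0.32 and 2.63 ± 0.32. Fabp6, the bile acid-binding protein of the ileum, rose by 2.65 ± 0.37, with the highest difference, 3.89, in mouse 1. In the authors' processed values, with no background subtraction, the changes of the dimmer of these genes were smaller: Reg3g rose by 1.48, Sis by 1.80, Fabp6 by 1.42, Myl7 by 1.91, Arg1 by 2.16 and Osr2 by 2.21.

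The largest fall was that of Fcmr, the receptor for IgM on B cells, which was 18.2-fold lower (-4.18 ± 0.25 log2, SE, n = 3 pairs, limma adjusted p = 0.00204). Other genes of B cells among the 10 largest falls were Cxcr5, the receptor that guides B cells into follicles (-2.66 ± 0.16, detected on 2 of 3 polyp arrays), Fcrla (-2.39 ± 0.12) and Cd79a, a signalling chain of the B cell receptor (-2.37 ± 0.19). Genes of T and cytotoxic cells were Ifng, which encodes interferon gamma (-2.78 ± 0.49), the chemokine Ccl5 (-2.77 ± 0.18), the granule protein Nkg7 (-2.39 ± 0.24) and the CD8 beta chain Cd8b1 (-2.35 ± 0.23). Retnla, a secreted protein of alternatively activated macrophages, fell by 2.64 on the log2 scale, and the kinase gene Srpk3 by 2.55. In the authors' processed values Fcmr changed by -2.90, Cxcr5 by -1.24, Srpk3 by -1.21, Cd79a by -1.29, Fcrla by -1.51 and Ifng by -1.76. Ifng had the highest adjusted p of the 20, 0.0232, which became 0.0576 in the authors' processed values. With mouse left out of the model, 15 of the 20 still passed the test, and Ifng (limma adjusted p = 0.277), Ccl5 (0.226), Nkg7 (0.247), Cd8b1 (0.172) and Fabp6 (0.0593) did not. With a trended, robust variance prior, 15 of the 20 passed, without Lgals2 (limma adjusted p = 0.0749), S100a9 (0.0678), S100a8 (0.0828), Fabp6 (0.091) and Ifng (0.176).

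**Figure D1:**
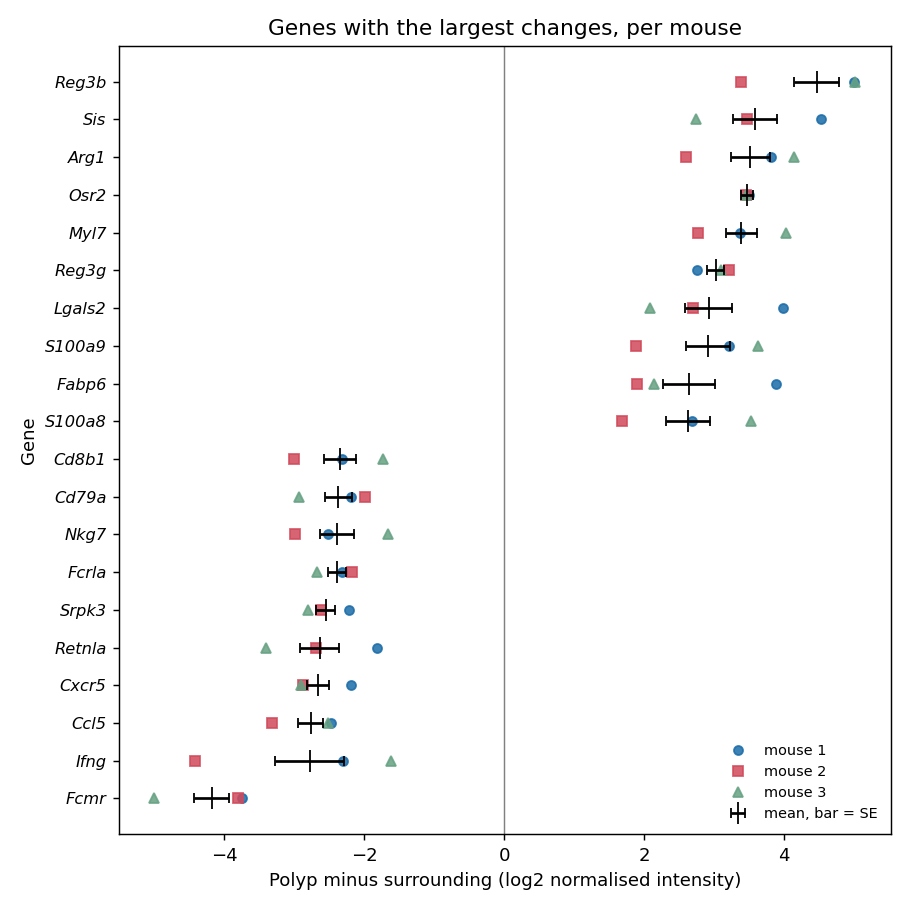
Polyp minus surrounding log2 normalised intensity (x axis) of the 10 genes with the largest rise and the 10 with the largest fall (y axis), with 1 point for each of the 3 mice and the fitted mean with its SE as a bar. All points lie on the same side of 0 as their mean, as the rule that picked the genes required, and the highest is that of Reg3b in mouse 3, at 5.03.

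Gene lists for 16 cell types and 18 functions were fixed before the data were examined, and 32 of the 34 had enough tested members for camera, a test of a list against all other genes. With camera's preset correlation between genes, 20 lists changed, 6 higher and 14 lower. With the correlation estimated from these arrays, no list passed: the lowest adjusted p was 0.384, and the value of each of the 20 lists is given with it. This form rests on 2 residual degrees of freedom and had little power over 32 lists. Correlation alone was not the reason: the epithelial list, with an estimated correlation of 0.00131, went from an adjusted p of 0.00375 in camera to 0.384. The failure to pass therefore neither backs nor overturns a call. By fry, which asks whether the genes of a list move together on balance, 12 lists passed, 1 of which, NADPH oxidase and phagocyte killing (adjusted p = 0.044), had not passed in camera. The count hangs on the threshold. The neutrophil, regulatory T cell, B cell, epithelial, hypoxia and T helper lists all had a fry adjusted p of 0.0499, and 14 lists lay at or under 0.06. For camera with the preset correlation, the 3 other splits of the 6 samples that part all pairs gave 12, 15 and 16 lists and those that part 1 pair gave up to 21, while none of them gave a changed probe in limma. With the mouse term kept, a split that parts 1 pair estimates the real difference of that mouse. In all splits but the real one, real differences also enter the residual spread. Their counts are therefore not those of groups without a difference. With mouse left out of the model, 4 of the 8 neutrophil members that rose still passed in limma, as did 5 of 8 antimicrobial, 4 of 12 endothelial and 3 of 10 MHC class II members. In the interferon, regulatory T cell, macrophage, epithelial and EGF receptor lists, 0 members then passed. List medians also depended on the background step. In the authors' processed values the B cell median was -0.83, the T cell median -0.86, the NK and cytotoxic cell median -0.36 and the neutrophil median 0.48. The medians there were -0.25 for regulatory T cells, -0.40 for T helper and innate lymphoid genes, -0.15 for dendritic cells, -0.10 for plasma cells, -0.51 for smooth muscle, -0.59 for other chemokines and -0.47 for interferon genes. Some genes stand in several lists, such as S100a8, S100a9, Lcn2, Ccl5, Ifng and H2-Ob.

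Of 16 tested T cell markers, 15 fell and 1 did not pass the test, with a list median of -1.40; adjusted over the list alone, 16 fell. Cd27 and Cd2, receptors that help activate T cells, fell by 1.90 and 1.75 on the log2 scale, and Cd3g, a chain of the T cell receptor complex, by 1.74. The list had an adjusted p of 1.44e-14 in camera with the preset correlation and an adjusted p of 0.384 with an estimated correlation. Of 15 B cell markers, 13 fell (14 adjusted over the list alone), with a median of -1.65 and an adjusted p of 1.88e-12, against an adjusted p of 0.384 with an estimated correlation. Of 10 markers of NK and cytotoxic cells, 7 fell (8 adjusted over the list alone), among them the receptor genes Klrd1 (-1.58 ± 0.12) and Klre1 (-1.20 ± 0.12, detected on 1 polyp array). Over all probes 3 did not pass, namely Klrb1c (-0.02), Prf1 (0.01) and Eomes (-0.31). Ncr1, Gzma and Gzmb were detected on too few arrays to be tested. The list therefore does not show whether NK cells or cytotoxic T cells changed. The list median was -1.08, with an adjusted p of 3.7e-06 and an adjusted p of 0.424 with an estimated correlation. With mouse left out of the model, 0 of the T cell, 9 of the B cell and 1 of the NK and cytotoxic cell members passed.

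Of 7 regulatory T cell markers, 5 fell, also when adjusted over the list alone, with a median of -0.53. The lineage factor Foxp3 fell by 0.53 on the log2 scale and the costimulatory receptor Tnfrsf4 by 0.90, and Gpr83, not detected on any polyp array, was at least 1.25-fold lower. Other, dimmer Foxp3 probes changed by only -0.16 and -0.04 and did not pass the test (limma adjusted p = 0.356 and 0.844). Camera gave this list an adjusted p of 0.00168, and 0.384 with an estimated correlation; 0 members passed without mouse 2 and 1 without mouse 3. Of 10 genes of T helper and innate lymphoid cells, 5 fell (7 adjusted over the list alone), with a median of -0.98, among them the chemokine receptor Ccr6 (-1.91 ± 0.13), the lineage factor Gata3 (-1.12 ± 0.09) and the interleukin 7 receptor Il7r (1.99-fold lower). In camera its adjusted p was 2e-05, and 0.384 with an estimated correlation; without mouse 1, 8 members passed. Of 10 plasma cell markers, 3 fell, namely Irf4, Mzb1 and Tnfrsf13b (3 fell and 1 rose adjusted over the list alone), with a median of -0.34. As a list it had an adjusted p of 0.0342, and 0.752 with an estimated correlation, and its call was lost without mouse 2 (adjusted p = 0.0738) and without mouse 3 (adjusted p = 0.171, median -0.15); without mouse 1, 5 members fell. The plasma cell call did not rest on single mice alone: it held in 7 of 18 alternatives (adjusted p from 0.000362 to 0.752) and was also lost with no background correction (0.0723), in the authors' processed values (0.0723), with an offset of 50 (0.0516), cyclic loess (0.0741), a trended, robust prior (0.0519) and both stricter filters on dim probes (0.207 and 0.0845).

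Genes of antigen presentation by MHC class II also fell: 10 of 15 passed the test (14 adjusted over the list alone), with a median of -0.64. The largest falls were in H2-Ob (-2.27 ± 0.23), H2-DMb2 (-2.02 ± 0.12) and H2-Oa (-1.68 ± 0.10), which encode chains that control peptide loading, and the master regulator Ciita fell by 1.00 on the log2 scale. The list's adjusted p was 5.02e-09, and 0.424 with an estimated correlation; 13, 5 and 3 members passed without mice 1, 2 and 3. Of 9 dendritic cell markers, 3 fell, namely Itgae, Ccr7 and Clec10a (4 adjusted over the list alone). Over all probes 6 did not pass, among them Zbtb46 (0.06), Irf8 (-0.14) and Siglech (-0.13). Itgax, Flt3, Clec9a and Xcr1 were detected on too few arrays to be tested. The dendritic cell median was -0.37, with an adjusted p of 0.0114 and an adjusted p of 0.384 with an estimated correlation. Without mouse 2, 1 member fell, and without mouse 3, when the median was -0.10, 1 fell. Of 18 monocyte and macrophage markers, 3 fell, the folate receptor Folr2 (-1.34 ± 0.26), Fcgr4 (-0.57 ± 0.09) and Ms4a7 (-0.56 ± 0.13), and 5 when adjusted over the list alone. The macrophage median was -0.36, with an adjusted p of 0.00209 and an adjusted p of 0.67 with an estimated correlation. Its members that fell numbered 8 without mouse 1, 0 without mouse 2 and 1 without mouse 3, and the median without mouse 3 was -0.20.

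Neutrophil markers moved the other way. Of 14 tested, 8 rose and 6 did not pass (10 rose adjusted over the list alone), and all 14 had values above 0, with a median of 1.05. Beside S100a8 and S100a9, the lectin receptor Clec4d rose 2.82-fold, the iron-binding protein Lcn2 by 1.64 ± 0.15 and the chemokine receptor Cxcr2, detected on 1 surrounding array, by 1.32 ± 0.12. Camera gave this list an adjusted p of 1.59e-07, and 0.384 with an estimated correlation. Granule genes of maturing neutrophils, Mmp8, Ngp, Camp, Mpo and Elane, were detected on too few arrays to be tested. Of 12 antimicrobial protein genes, which share S100a8, S100a9 and Lcn2 with the neutrophil list, 8 rose (10 adjusted over the list alone), with a median of 0.89. Reg3a, not detected on any surrounding array, was at least 1.42-fold higher. In camera its adjusted p was 2.38e-06, and 0.384 with an estimated correlation. Ptprc and lymphocyte genes, by contrast, fell in these same samples.

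Of 9 genes of the NADPH oxidase and phagocyte killing, 2 rose and 3 fell (3 and 4 adjusted over the list alone): haptoglobin, Hp, rose by 1.55 ± 0.11, and the oxidase subunits Rac2 (-1.05 ± 0.10), Ncf1 (-0.63 ± 0.09) and Ncf4 (-0.60 ± 0.11) fell. The list did not pass (median -0.22, adjusted p = 0.565). Of 13 genes of myeloid suppression and alternative activation, 3 rose and 2 fell (3 and 3 adjusted over the list alone), and the list did not pass (median -0.13, adjusted p = 0.624). Its members moved far apart: Arg1, its isoenzyme Arg2 (1.00 ± 0.22) and Chil3, which the neutrophil list also holds, rose, while Retnla and the checkpoint ligand Cd274 (-0.92 ± 0.15) fell. Of 8 mast cell and basophil markers, 1 rose, the transcription factor Gata2 (0.67 ± 0.13), and 1 when adjusted over the list alone. The list median was 0.61 and did not pass (adjusted p = 0.0991), with medians of 1.95, 0.36 and -0.39 in mice 1, 2 and 3; it passed without mouse 2 (adjusted p = 0.032) and without mouse 3 (adjusted p = 0.00729), and in all in 6 of 18 alternatives (adjusted p from 0.000255 to 0.968). The eosinophil list, with Prg2 and Il5ra as its 2 tested members, and the erythroid list, with 4, were too short for the list test, and no member of either passed as a single gene over all probes; adjusted over the list alone, 1 erythroid gene, Slc4a1, fell.

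Markers of cells that should lack CD45 moved as well, beside the leukocyte genes. All 12 endothelial markers rose, also when adjusted over the list alone, with a median of 0.81. Robo4, Emcn, Eng and Esam, surface proteins of vessel endothelium, rose by 1.01 ± 0.10, 0.99 ± 0.10, 0.91 ± 0.10 and 0.80 ± 0.09. As a list it had an adjusted p of 4.75e-10, and 0.384 with an estimated correlation; 5 members passed without mouse 2 and 7 without mouse 3. Of 7 smooth muscle markers, 4 fell (5 adjusted over the list alone), with a median of -0.82, led by the contractile genes Actg2 (-2.06 ± 0.17), Myh11 (-1.73 ± 0.20) and Des (-1.03 ± 0.14). The list's adjusted p was 0.000298, and 0.424 with an estimated correlation, and the median without mouse 3 was -0.52. Of 14 fibroblast markers, 1 rose and 1 fell, also when adjusted over the list alone, the matrix protein Sparc (1.15 ± 0.12) and the collagen Col6a1 (-0.65 ± 0.15), and the list did not pass (median -0.10, adjusted p = 0.596).

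Epithelial transcripts were bright in both groups. Krt19, a keratin of simple epithelium, had a mean normalised log2 intensity of 12.1 ± 0.15 (SD, n = 3) in polyp samples and 11.5 ± 0.07 in surrounding samples. Of 15 epithelial markers, 3 rose (4 adjusted over the list alone), namely Krt19 (0.60 ± 0.09), Krt18 (0.51 ± 0.10) and the transcription factor Elf3 (0.50 ± 0.10), with a list median of 0.21. Camera gave this list an adjusted p of 0.00375, and 0.384 with an estimated correlation; 2, 0 and 0 members passed without mice 1, 2 and 3. Of 10 markers of goblet and secretory cells, 2 fell, also when adjusted over the list alone, the goblet cell proteins Clca1 (-1.34 ± 0.16) and Zg16 (-0.52 ± 0.12). This list did not pass (adjusted p = 0.834), and its median of 0.13 lay above 0 while its mean of -0.10 and its test pointed down. Of 6 genes of the EGF receptor family, 4 rose, also when adjusted over the list alone: the receptor Egfr (0.89 ± 0.12) and the ligands Btc (0.89 ± 0.09), Nrg1 (0.64 ± 0.14) and Nrg4 (0.60 ± 0.11), both neuregulins being detected on 2 surrounding arrays. Their median was 0.62, with an adjusted p of 0.00131 and an adjusted p of 0.384 with an estimated correlation; 2 rose without mouse 2 and 1 without mouse 3, and the median in the authors' processed values was 0.18.

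Of 22 chemokines other than those that attract neutrophils, 8 fell and 2 rose (13 and 3 adjusted over the list alone), with a median of -1.01. The falls included Ccl5 and the B cell attractant Cxcl13 (-1.68 ± 0.13, detected on 2 polyp arrays), and the rises were Ccl25, a small-intestinal chemokine (1.84 ± 0.20), and Ccl17 (1.09 ± 0.14). In camera its adjusted p was 0.00209, and 0.645 with an estimated correlation; 13 fell without mouse 1 and 4 without mouse 2. Of the 5 tested chemokines that attract neutrophils, 0 passed in limma, also adjusted over the list alone, and the list did not pass either (median -0.53, adjusted p = 0.63). Cxcl1 differed by 1.26, -1.19 and -1.67 and Ccl3 by 0.32, -1.53 and -1.90 in mice 1, 2 and 3; without mouse 1, 3 members fell and the list passed (adjusted p = 0.00371). Of 17 inflammatory cytokines, 5 fell (5 fell and 3 rose adjusted over the list alone), among them the lymphotoxin genes Ltb (-1.36 ± 0.10) and Lta (-0.90 ± 0.12) and Tnfsf14 (-0.89 ± 0.10). Another, dimmer Tnfsf14 probe changed by only -0.14 and did not pass the test (limma adjusted p = 0.394). The cytokine list did not pass (median -0.05, adjusted p = 0.24), but passed in 2 of 18 alternatives, without mouse 1, when 9 members fell (adjusted p = 9.56e-05), and with median scaling (adjusted p = 0.00258).

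Of 19 genes of the type I interferon response, 5 fell (11 adjusted over the list alone), and all 19 had values below 0, with a median of -0.74. Isg15 and Rsad2, induced by viruses and interferon, fell by 1.47 and 1.41 on the log2 scale. As a list it had an adjusted p of 3.48e-07, and 0.604 with an estimated correlation. Its medians in mice 1, 2 and 3 were -1.50, -0.62 and -0.21; without mouse 1 the median was -0.40 and without mouse 2 only 2 members passed. Of 18 NF-kappaB targets, 1 fell, also when adjusted over the list alone, the signalling adaptor Traf1 (-0.56 ± 0.11), with a median of -0.29. The list's adjusted p was 0.0386, and 0.752 with an estimated correlation; its call was lost without mouse 2 (adjusted p = 0.352) and without mouse 3 (adjusted p = 0.138), and without mouse 1 11 members fell. The NF-kappaB call held in 9 of 18 alternatives (adjusted p from 1.69e-06 to 0.752), and was also lost with cyclic loess (0.0741) and with a trended, robust prior (0.107). Of 20 immediate early and heat shock genes, 1 fell, also when adjusted over the list alone, the nuclear receptor Nr4a2 (-1.39 ± 0.21), with a median of -0.39. This list's adjusted p was 0.00375, and 0.752 with an estimated correlation. Its medians were 0.14, -0.61 and -0.69 in mice 1, 2 and 3; 14 members fell without mouse 1, when the median was -0.64. Without mouse 2 the median was -0.20, and without mouse 3 it was -0.22 and the call was lost (adjusted p = 0.121).

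Of 24 hypoxia and glycolysis genes, 5 rose, also when adjusted over the list alone, led by the oxygen sensor Egln3 (1.01 ± 0.10) and the glycolytic enzymes Pfkp (0.67 ± 0.09) and Pgam1 (0.49 ± 0.09). The list median was 0.18, with an adjusted p of 0.00491 and an adjusted p of 0.424 with an estimated correlation; 1 member passed without mouse 2 and 1 without mouse 3. With arrays scaled to the same median, 2 members rose and 2 fell. The remaining lists did not pass. Of 17 genes of IL-1 signalling, 1 rose and 1 fell, also when adjusted over the list alone, the receptor antagonist Il1rn (1.21 ± 0.16) and Il18r1 (-0.66 ± 0.16), with a median of 0.04 and an adjusted p of 0.645. Of 15 pattern recognition receptors, 2 rose and 2 fell (2 and 3 adjusted over the list alone), with Clec4d and Tlr4 (0.43 ± 0.10) higher and Tlr7 (-0.87 ± 0.16) and Nod1 (-0.54 ± 0.09) lower, and the median was 0.05 (adjusted p = 0.852). Of 13 extracellular proteases and inhibitors, 2 rose and 1 fell (3 and 1 adjusted over the list alone), namely Mmp10 (1.54 ± 0.12), the inhibitor Timp1 (0.81 ± 0.15) and Mmp13 (-0.72 ± 0.11), with a median of 0.05 and an adjusted p of 0.63. None of 25 cell cycle genes (median -0.10, adjusted p = 0.172) and none of 20 ribosomal protein genes (median -0.03, adjusted p = 0.624) passed, also when adjusted over the list alone.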

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

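All alternatives were chosen before the data were examined. No count, list or gene picked by the naming rule turned its direction past the threshold in any of them. Genes named outside the rule were not rerun. The median over all probes stayed within 0.1 log2 units of 0. The 1399 changed probes became 183 with no replicate block, that is with mouse left out of the model, and all 183 were among the 1399. Array weights gave 2252, of which 1395 were shared. Leaving out a mouse, which also leaves fewer pairs and another prior, gave 412 to 1927. The 323 probes changed at least 2-fold became 102 without background correction, 102 in the authors' processed values, 177 with an offset of 50 and 140 with no replicate block, and 276 to 399 without a mouse. A background level left in, or a larger offset, shrinks log2 differences of dim probes by construction. With a fixed mouse term left out, differences between mice enter the residual spread. The cause of the count with array weights was not tested. With median scaling eBayes found an infinite prior, against a prior of 4.04 degrees of freedom in the reported fit, so that its adjusted p-values treat all probes as equally variable and say little about single genes. The 20 changed gene lists became 0 in camera with an estimated correlation and 12 by fry, and 18 to 22 without a mouse. Camera with an estimated correlation rests on 2 residual degrees of freedom and had little power. With no replicate block 19 lists passed, and the NF-kappaB list was the call that was lost (adjusted p = 0.084). Tests with mouse as a random block or a trended prior took the moderated statistics of the fit for the lists. Over all alternatives 1770 values of named genes stayed on their side of the threshold, 218 lost and 69 gained a call; for lists these numbers were 517, 46 and 10. Signal over background limits the dim genes: the polyp sample of mouse 3 had the fewest detected probes, 12657.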

Other observations

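The gene panels in this part were drawn up after the main results were seen, and the tests of macrophages and of neutrophils against T cells, of small-intestinal against epithelial genes and of the stress list in mouse 1 were chosen after the results they use were seen. In a panel of 20 general leukocyte genes, of 18 tested, 16 fell and 0 rose, with a median of -0.67. Among them were Ikzf1, a transcription factor of lymphoid development (-1.04 ± 0.10, SE, n = 3 pairs, limma adjusted p = 0.00378), Coro1a, an actin regulator of leukocytes (-0.83 ± 0.11), and Laptm5 (-0.63 ± 0.12). Itgb2 and Ptpn6 did not pass, at -0.24 and -0.30.

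A panel of 37 small-intestinal genes, drawn up without those that had drawn attention, had 15 tested members. Of these, 7 rose, 0 fell and 8 did not pass the test, with a median of 0.47. A probe could pass the detection filter through the arrays of 1 group alone, so the median speaks only for the tested genes of the panel. No set test was run on this panel, and Dpp4 and Khk had values below 0. The risers included Gsta1 (1.04 ± 0.12), the trehalase gene Treh (1.18 ± 0.15), and the bile acid receptor Nr1h4 (0.72 ± 0.10) and transporter genes Slc51a (0.87 ± 0.13) and Slc51b (0.60 ± 0.13). In a panel of 32 large-intestinal genes, 2 of the 17 tested rose and 2 fell, with a median of -0.05. Sult1a1 (-1.48 ± 0.11) and Cyp2c55 (-1.11 ± 0.09) fell, and Hoxd9 and Mgat4c rose. Car4 and Aqp8, of surface cells of the large bowel and named after their values were seen, fell by 2.21 and 1.34 on the log2 scale.

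Lymphocyte genes were lower in polyp samples while neutrophil genes were higher. A lower share of all CD45-positive cells would lower both, and macrophage genes too. The first test set the macrophage list median against that of T cells. It lay above by 1.14 log2 units on average over the mice (SD 0.70, n = 3), with 1.59, 1.49 and 0.33 in mice 1, 2 and 3, which is under 2 SD and did not decide. A second test, chosen because the first did not decide, used the neutrophil list, whose median lay 2.57 above that of T cells (SD 0.65); a lower share of leukocytes as the only change is argued against by this value, while a part in the falls stays open, as Ptprc and 16 of the 18 leukocyte panel genes fell.

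Fewer lymphoid follicles in the polyp pieces may also lower B and T cell genes. A panel of 20 follicle genes had a median of -0.13 over its 8 tested members. The bound set beforehand would have ruled this explanation out at such a median, but the bound was ill chosen, since members went both ways: Tnfrsf11b (1.04) and Madcam1 (0.91) rose and Bcl6 (-0.73) fell, and a median near 0 over such members decides nothing. Follicle number and a change of lymphocytes at the polyp, which the tissue groups would allow, cannot be told apart here.

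A set of 10 genes known from the small intestine, Sis, Fabp6, Ccl25, Slc7a9, Abcg5, Cps1, Naaladl1, Apoa1, Tm4sf4 and Tm4sf5, was singled out after their values were seen. All but Apoa1, which did not pass the test, rose. The medians of all 10 were 2.70, 1.89 and 1.30 in mice 1, 2 and 3. A larger share of epithelial cells as the whole cause would raise epithelial genes by about as much, but the 15 epithelial markers lay between -0.10 and 0.60 and the 10 genes 1.74 above their median (SD 0.67, n = 3). Against the 7 dimmer epithelial markers, a comparison also chosen after the values were seen, the gap was 1.61 (SD 0.66). The rise of these 10 genes was thus larger than that of the epithelial markers. But the genes were singled out with their values in view, so the size of either gap was in part set by that choice. The separate panel of small-intestinal genes, with a median of 0.47, lay nearer the epithelial median of 0.21. Whether a larger share was the whole cause, or had a part in the rise, is therefore not decided. Another position along the gut could raise small-intestinal genes in general. The separate panel had a median of 0.47, between the bounds of 0.25 and 0.5 set beforehand, and so left this open, as does a change of epithelial cells in the polyp itself, which was not tested.

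Mouse 1 stood apart in chemokine and cytokine genes: 16 of 22 chemokines and 13 of 17 cytokines had their highest polyp minus surrounding difference in this mouse. Handling or dissociation stress that differed between samples may be a source, and of the 20 immediate early and heat shock genes 95% (19) had their highest difference in mouse 1, against 34.1% of all genes. Hspa1a, a heat shock gene, differed by 0.08, -2.04 and -2.51 in mice 1, 2 and 3. Hspa1a varied more among polyp samples (SD 1.40, n = 3) than among surrounding samples (SD 0.36). The same held for Egr2 (1.14 and 0.38), Dusp2 (1.30 and 0.63) and, less so, Nr4a2 (1.09 and 0.87). For these genes the mice thus differed more in the polyp samples than in the surrounding ones. This leaves a stress difference among the polyp samples possible, but inflammation that differed between mice stays open and was not tested.

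The 6 samples can be split in 10 ways, the real one included, too few for a share under 0.05. The real split gave 1399 changed probes and the highest of the others 0, so that 1 split reached the real count. For at least 2-fold changes the real split gave 323 and the highest other 0, again 1 split. In the other splits the real polyp differences enter the residual spread, which by itself holds their counts down. The counts of 0 are therefore no measure of what chance would give. For gene lists in camera with the preset correlation the real split gave 20 and the highest other 21, and 3 of the 10 splits gave 20 or more. The splits with 21 parted only the pair of mouse 3. The 3 other splits that part all pairs gave 12, 15 and 16 lists. The 6 splits that part only 1 pair gave 15 to 21. With the mouse term kept, such a split estimates the real polyp difference of the parted mouse, up to its sign. The 3 others that part all pairs reverse 1 mouse and also carry real differences. The list counts of these splits are therefore not those of groups without a difference, and decide nothing about chance. These splits were fitted with the mouse term kept.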
